A study of Homo sapiens with 17 samples.

How the data were processed

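Total RNA of the lymphoma lines Karpas-422 and WSU-DLCL2 was sequenced by the authors, who deposited read counts per gene, 1 file for each of 15 libraries. Per the submitters' processing notes, STAR 2.5.3a and RSEM (with no version) were used, and the genome build was GRCh37 (hg19). The order and settings of these steps, the annotation, the counting program, the library kit and its strand are not given in the sources used here. The values are whole numbers, and each file ends in 5 summary lines of the kind that a read-counting program writes, so they were used as raw counts and were not normalized before deposit. Each file held 63677 genes by Ensembl identifier. Symbols were taken by identifier from a gene name table and GENCODE 29; 52526 genes had a symbol, and the 11151 without one held 0.862% of the counts. GENCODE 29 is on GRCh38, so it was used for names, gene types, numbers of transcripts and exonic lengths alone, and no coordinates are given. As strand is not stated, reads of overlapping and antisense genes cannot be told apart, and paralogs such as the HLA genes may share reads.

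The summary lines (reads outside genes, ambiguous, of low quality, unaligned, or without a unique alignment) made up 60.9% to 70.2% of all lines' reads in the 9 shallow libraries and 27.3% to 29.7% in the 6 deep ones. They stayed out of library sizes and tests. Depth, as counts assigned to genes, was 6689320 to 8897051 in the former and 21233752 to 37286727 in the latter. Counts are of reads, not of unique molecules, so intervals and floors cover counting error only. Shares of reads are given relative to the reads they could be counted with, as means with SD.

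The labels list 17 samples. Titles and source names gave the groups: untreated and A-485 (48 h) in each line, and 3 clones labelled BCL11A knockout. For replicate 3 of untreated WSU-DLCL2 the labels list 3 sequencing runs, which shared 1 count file and were used as 1 library; 2 sample records thus have no file of their own here. Its title and its treatment entry disagree, and it was grouped by title. Replicates were compared by a chi-square per gene over genes with at least 20 counts in a pair; the lowest value was 1.20, for A-485 replicates 2 and 3 in Karpas-422, and no pair was counted as 1 sample.

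Comparisons were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups compared, robust quasi-likelihood fits and two-sided tests, Benjamini-Hochberg adjustment over the genes kept, and a threshold of 0.05. Only the groups compared entered a fit. Standard errors of log2 fold changes are the fold change divided by the square root of F. The interaction of line and treatment was tested in 1 fit of 4 groups. CPM given for a comparison are TMM-scaled, as are those of HLA-DQA1 and FAS per library and those of untreated WSU-DLCL2 replicates 1 to 3, scaled among themselves; CPM of BCL11A per library, of the kinds of library and across comparisons are not. The numbers 1 to 3 of the replicates were not used as pairs. Overlaps of calls were set beside n1 × n2 / N per direction and Fisher's exact test, and for the comparisons that share untreated libraries beside 50 simulations of unchanged groups. Genes at 0 in all libraries of a group are given as bounds against a floor of 3 counts over the group, and genes at 1 to 3 counts as ratios with 95% binomial (exact Clopper-Pearson) counting intervals.

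Before the data were examined, the groups, tests, alternatives, named-gene rule and 24 gene lists with 483 members were fixed. The lists were B cell identity, germinal centre, plasma cell, MHC class II, interferon response, MYC targets and ribosome biogenesis, G2/M, DNA replication and G1/S, BCL2 family, p53 targets, cholesterol biosynthesis, ATF4 stress response, endoplasmic reticulum chaperones, replication-independent histones, histone acetylation, Polycomb, globins, NF-kB targets, BCL11A neighbours, lymphoma oncogenes, T and NK cell, myeloid, epithelial and fibroblast markers, and mitochondrially encoded mRNAs. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry, each adjusted over the lists. Fry asks whether a list's genes move, on balance, one way, and does not compare the list with other genes. Counts "adjusted over the list alone" use the members' edgeR p. The named genes were, per comparison, the 6 largest rises and 6 largest falls among called protein-coding genes with at least 10 CPM in the higher group and no overlap between groups (the last not asked of the interaction), 9 fixed genes (BCL11A, EP300, CREBBP, EZH2, MYC, BCL2, BCL6, PRDM1 and IRF4), and up to 3 members of each list with the smallest p. The overlaps name up to 6 protein-coding genes per direction called in both comparisons, ranked by the smaller of their 2 absolute log2 fold changes. SERPINA9 is among them. TCF7 in Karpas-422, and ACTB, RPL13A, LCP1 and TOP1 for the kinds of library, are named outside this rule, after their values were seen. So are the list members named for untreated WSU-DLCL2 replicate 3 alone. Some genes that the rule names are not reported here.

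The tests were tried on simulated data with known changes, 50 genes per fold. Of genes changed 1.5, 2, 4 and 8-fold, 50%, 80%, 98% and 96% were recovered for Karpas-422 (11462 genes, 10 false calls). For A-485 in WSU-DLCL2 the shares were 2%, 26%, 60% and 90% (14282 genes, 5 false), for the knockout 2%, 16%, 66% and 90% (15835 genes, 7 false), and for the knockout without untreated replicate 3 26%, 58%, 84% and 94% (16219 genes, 18 false). For the interaction they were 0%, 16%, 60% and 62% (14202 genes, 4 false). A simulated list of 20 genes was called in each of the 4 group comparisons tried, and 1 of 21 other lists was called for A-485 in WSU-DLCL2, 0 in the others.

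Alternatives were DESeq2's size factors, library sizes alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 15 libraries in 1 fit, each library left out, a log2 fold change of at least 1, an adjusted p under 0.01, and for lists the estimated correlation and fry. Chosen after the data were seen were fits on the 2438 protein-coding genes with 1 annotated transcript, the named genes and lists without untreated WSU-DLCL2 replicate 3, and the overlap of A-485 in Karpas-422 with the knockout. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads and chromatin data were not analysed here.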

Results

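RNA-seq read counts per gene were examined in Karpas-422 and WSU-DLCL2, established human cell lines derived from diffuse large B cell lymphoma. The 15 libraries fell into 5 groups of 3: each line untreated, each line treated with A-485 for 48 h, and 3 clones of WSU-DLCL2 labelled as BCL11A knockouts. A-485 inhibits the catalytic activity of the histone acetyltransferases p300 and CBP, the products of EP300 and CREBBP. BCL11A encodes a zinc-finger transcription factor of the B lineage. The series concerns histone acetylation and chromatin folding at oncogenes. The counts assigned to genes reached 7792197 to 8897051 per library for Karpas-422 with A-485, 6949770 to 8186582 for untreated Karpas-422 and 6689320 to 7086106 for WSU-DLCL2 with A-485. They reached 29669098 to 34904926 for the clones and 21233752 to 37286727 for untreated WSU-DLCL2. For replicate 3 of the untreated WSU-DLCL2 group the labels disagree: its title and source name give the untreated line, and its treatment entry gives A-485. It was grouped by its title, and the comparisons that use it are given with and without it. The clones are separate by label; for the other replicates no label says whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

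The libraries were of 2 kinds, and each group was wholly of 1 kind. The kind followed A-485 within WSU-DLCL2 but not within Karpas-422. The 9 shallow libraries (all of Karpas-422, and WSU-DLCL2 with A-485) had 50.045% to 57.0% of reads without a unique alignment and 2.51% to 14.6% unaligned. The 6 deep libraries (untreated WSU-DLCL2 and the clones) had 7.73% to 9.24% without a unique alignment and 0 unaligned. The cytoskeletal gene ACTB stood at 3.20 to 31.9 CPM (counts scaled by the library total) in the shallow libraries and at 3432 to 9994 CPM in the deep ones. The ribosomal protein gene RPL13A stood at 0.116 to 0.897 against 806 to 1169 CPM, and the leukocyte actin-bundling gene LCP1 at 5.40 to 13.1 against 3507 to 6199 CPM. TOP1, which encodes DNA topoisomerase I, went the other way, with 2113 to 8367 against 278 to 408 CPM. Across genes, Spearman's rho between libraries of the 2 kinds lay between 0.480 and 0.627. The WSU-DLCL2 libraries with A-485 correlated with those of Karpas-422 at 0.795 to 0.830, and with those of untreated WSU-DLCL2 at 0.607 to 0.627. In Karpas-422 and in the knockout comparison both groups were of the same kind. A-485 in WSU-DLCL2 was compared across the 2 kinds, so treatment and kind of library cannot be told apart there.

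**Figure D1:**
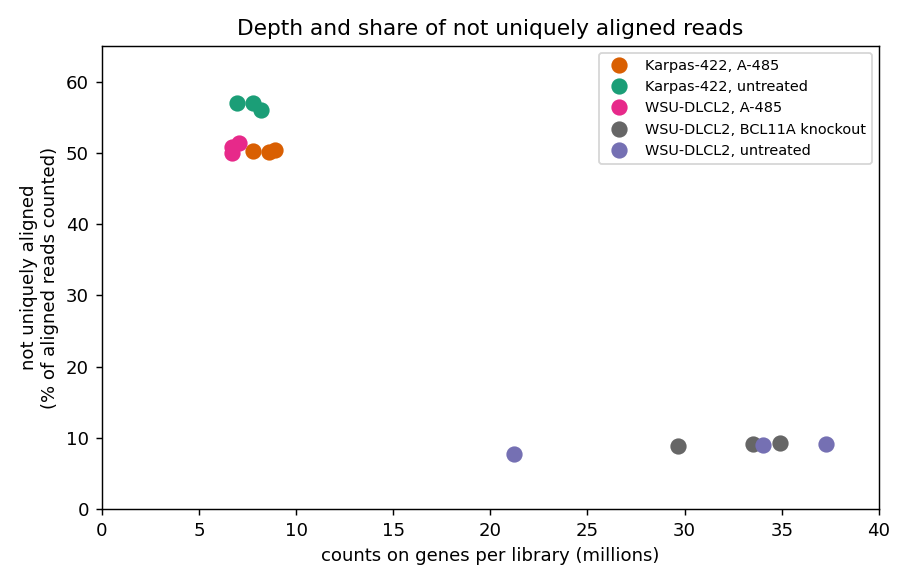
Depth and unique alignment of the 15 libraries. Each point is a library, with counts assigned to genes on the horizontal axis and the percentage of reads without a unique alignment on the vertical axis, coloured by group; the 9 shallow libraries lie between 50.045% and 57.0%, and the 6 deep libraries between 7.73% and 9.24%.

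The first comparison addressed what inhibition of p300 and CBP did to gene expression in Karpas-422. All 27 tested members of the interferon response list rose with A-485. IFI44 rose 15.5-fold, from 5.31 ± 0.844 to 83.2 ± 6.15 CPM (mean ± SD, n = 3 libraries per group). Other genes fell: CD74, the invariant chain of MHC class II, went from 1282 ± 77.7 to 134 ± 7.996 CPM, and NPM1, a nucleolar protein gene controlled by MYC, from 842 ± 12.7 to 177 ± 1.51 CPM. The transcription factor gene SOX9 fell 61.9-fold, from 159 ± 17.2 to 2.57 ± 0.474 CPM, and the immediate-early gene EGR1, which has 1 annotated transcript, rose 14.8-fold, from 13.1 ± 0.951 to 195 ± 19.5 CPM.

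The interferon list (27 members up, 0 down, 27 up when adjusted over the list alone) had a median log2 fold change of 1.79. Its call in camera was lost with an estimated correlation (adjusted p = 0.126 with an estimated correlation). Besides IFI44 (3.95 ± 0.12, log2 fold change ± SE), the antiviral genes RSAD2 (3.14 ± 0.10) and IFIT2 (2.64 ± 0.08) had the smallest p in it. Of 22 MYC targets and ribosome biogenesis genes, 16 fell, 1 rose and 5 were not called, with the same 16 and 1 adjusted over the list alone. ODC1, the first enzyme of polyamine synthesis, fell by 2.66 ± 0.05 on the log2 scale, NPM1 by 2.25 ± 0.05, and the ribosome assembly gene RRS1 by 2.45 ± 0.06. Of 14 MHC class II genes, 9 fell (9 adjusted over the list alone), 0 rose and 5 were not called. They included CD74 (−3.26 ± 0.06), HLA-DRA (−2.30 ± 0.07) and CIITA (−2.21 ± 0.06), the transactivator of the class II genes. HLA genes share sequence, so their single values are uncertain. Of 18 germinal centre genes, 12 fell, 3 rose and 3 were not called (12 and 4 adjusted over the list alone). IRF8 went from 571 ± 16.7 to 97.4 ± 3.36 CPM and FOXO1 from 1152 ± 107 to 435 ± 7.02 CPM; P2RY8, a receptor that confines B cells to the germinal centre, fell by 2.46 ± 0.06 on the log2 scale. SERPINA9, a germinal centre marker, had 45 counts over the untreated libraries and 0 with A-485, which makes it at least 21.9-fold lower (floor of 3 counts over the group, counting error only).

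Smaller shifts were called for 4 further lists with the preset correlation alone. With an estimated correlation their adjusted p was 0.126 for B cell identity, ATF4 and DNA replication and 0.151 for plasma cells. Of 21 B cell identity genes, 13 fell and 4 rose, both overall and adjusted over the list alone. POU2F2 (−2.19 ± 0.05), SPIB (−1.60 ± 0.06) and VPREB3 (−2.54 ± 0.08), of which the first and second encode B cell transcription factors, had the smallest p. Of 16 amino acid stress genes under ATF4, 8 fell and 2 rose (8 and 2 adjusted over the list alone), among them TRIB3 (−2.08 ± 0.05) and the serine synthesis enzyme PSAT1 (−1.82 ± 0.05). Of 22 DNA replication genes, 12 fell and 6 rose (12 and 6 adjusted over the list alone), with FEN1 at −1.08 ± 0.05, MCM2 at −1.26 ± 0.06 and CDC6 at −1.12 ± 0.05. Of 10 plasma cell genes, 6 fell and 0 rose (6 adjusted over the list alone), with PIM2 at −1.65 ± 0.06, JCHAIN at −2.75 ± 0.22 and TNFRSF17 at −2.29 ± 0.18.

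**Figure D2:**
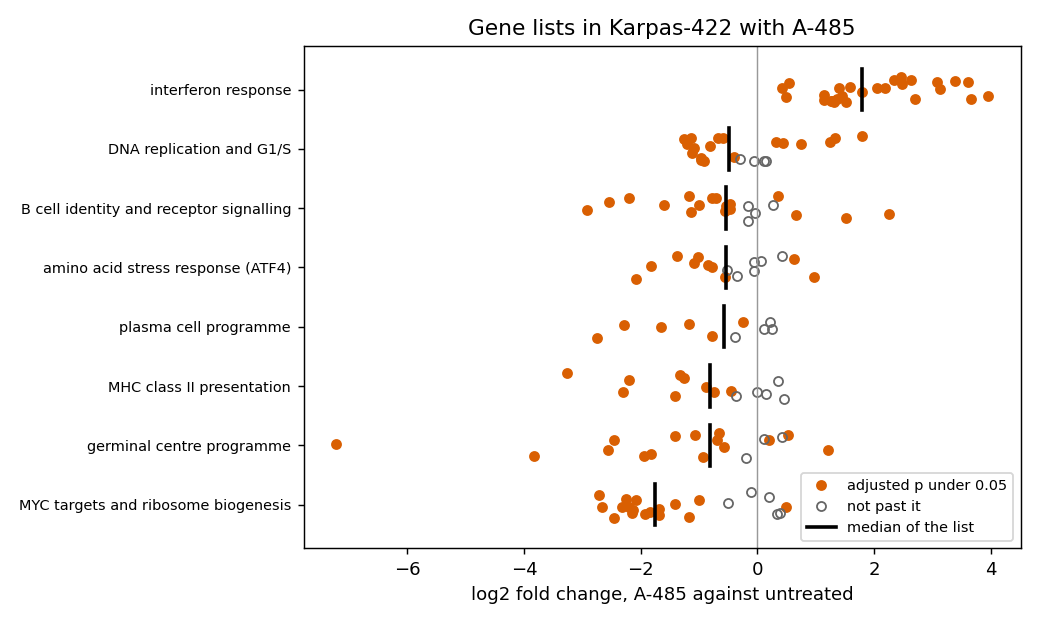
Log2 fold change, A-485 against untreated Karpas-422, of each tested member of the 8 lists that were called. Filled points passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each bar is the list's median; all 27 interferon genes lie above 0, and the median of the MYC targets lies at −1.76.

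Of the genes fixed beforehand, BCL11A fell by 1.33 ± 0.06 on the log2 scale (adjusted p = 1.65e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 165 ± 7.48 to 65.5 ± 0.808 CPM. MYC had few counts in both groups and fell from 6.35 ± 0.382 to 0.418 ± 0.128 CPM. In the shallow libraries ACTB also stood at only 3.20 to 31.9 CPM, so a low CPM there does not show low expression. EZH2, the catalytic subunit of Polycomb repressive complex 2, rose from 8.30 ± 1.34 to 44.3 ± 1.39 CPM. Of the genes of the enzymes that A-485 inhibits, CREBBP rose by 0.40 ± 0.06, and EP300 differed by 0.10 ± 0.13 (adjusted p = 0.498, same test). With library sizes alone CREBBP stood at 0.81 and EP300 at 0.52, and both were called. BCL6, the repressor that maintains germinal centre B cells, fell by 0.69 ± 0.10. BCL2 was lower by 0.38 ± 0.07 under TMM scaling and differed by 0.03 with library sizes alone. PRDM1 had 0 counts in all 6 libraries and IRF4 at most 3 in any, so neither was tested.

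By the rule of largest change, CFAP70 (4.28 ± 0.19), CCDC14 (3.86 ± 0.09), PDE1B (3.85 ± 0.20) and LUC7L2 (3.71 ± 0.23) also rose most, and NLRP4 fell by 6.15 ± 0.27. The remaining genes of that rule had 2 or 3 counts over the A-485 libraries. DNAI1 was 227-fold lower (95% counting interval 62.2 to 1879), TLE3 148-fold (40.4 to 1229.6), C4orf50 128-fold (43.2 to 623) and LGALS14 110.3-fold (37.3 to 539).

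In this comparison 8457 of 11846 genes changed (4459 up, 3998 down), of which 4090 changed at least 2-fold (2693 up, 1397 down), and 8713 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 8854 genes (74.7%), where chance gives 10%. With library sizes alone, the median of all genes moved by 0.41 upwards and the calls split into 6465 up and 2290 down; the directions given here are relative to TMM scaling. The medians of the 8 called lists kept their sign with either other scaling, and the germinal centre median was −0.81 also with SERPINA9 at its bound. With library sizes alone MHC class II stood at −0.40 (8 down, 3 up) and the germinal centre at −0.40 (12 and 5), and 4 lists were close to 0: B cell identity at −0.12 (8 down, 6 up), plasma cells at −0.17 (5 and 4), ATF4 at −0.13 (7 and 6) and DNA replication at −0.08 (10 and 7). In camera's test with the preset correlation, Benjamini-Hochberg adjusted p was 2.10e-16 for the interferon list, 9.40e-17 for the MYC targets, 6.42e-08 for MHC class II, 6.12e-06 for the germinal centre, 0.00281 for B cell identity, 0.00458 for ATF4, 0.0241 for DNA replication and 0.0326 for plasma cells. The MYC targets, MHC class II and germinal centre lists were also called with an estimated correlation (adjusted p = 0.0135, 0.0423 and 0.0455). The others were not: adjusted p = 0.126 with an estimated correlation for the interferon, B cell, ATF4 and DNA replication lists and 0.151 for plasma cells.

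A-485 moved with features of the libraries. Reads outside annotated genes made up 17.9% ± 0.693 of reads with A-485 and 9.28% ± 1.14 without, and reads without a unique alignment 50.3% ± 0.165 against 56.7% ± 0.603. The fold change varied with the number of annotated transcripts. Its median was 0.06 for genes with 1 transcript, −0.21 for 2 to 3, −0.18 for 4 to 6, 0.10 for 7 to 10, 0.39 for 11 to 20 and 0.66 for over 20 (Spearman's rho 0.185 over 11498 genes, which are not independent replicates). Among list members with at most 2 annotated transcripts, 4 of 4 interferon genes rose (median 1.44), and 2 of 2 MYC targets (median −2.33) and 2 of 2 MHC class II genes (median −1.78) fell. Of 5 germinal centre genes 2 rose and 2 fell, with a median of −0.20. Of the other called lists, 1 of 1 B cell identity gene, 1 of 1 plasma cell gene, 2 of 4 ATF4 genes and 1 of 2 DNA replication genes fell, and 0 rose.

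The other lists were not called in Karpas-422. NF-kB targets (7 tested, 4 up, 1 down, 4 and 2 adjusted over the list alone, adjusted p = 0.0562 in camera) held TNF, at 791 ± 55.2 against 251 ± 12.2 CPM, and LTA (1.63 ± 0.18), which lie next to each other. Among 21 lymphoma oncogenes, 3 rose, such as TCF4 (2.17 ± 0.09), and 14 fell (adjusted p = 0.0800 in camera). Of 11 BCL2 family genes 2 rose and 6 fell, including the pro-apoptotic BCL2L11 (−1.20 ± 0.05; adjusted p = 0.159 in camera). Of 16 endoplasmic reticulum chaperones 5 rose and 7 fell, with HSPA5 at −1.68 ± 0.06 and PDIA4 at −1.54 ± 0.06 (adjusted p = 0.169 in camera). Of 21 cholesterol genes 6 rose and 10 fell (adjusted p = 0.189 in camera). Of 22 histone acetylation genes 13 rose and 4 fell, with KAT2B at 0.70 ± 0.05 and HDAC4 at −1.46 ± 0.10 (adjusted p = 0.189 in camera). Of the 13 neighbours of BCL11A on chromosome 2p 8 rose and 4 fell, among them XPO1 (0.89 ± 0.09) and CCT4 (−1.43 ± 0.13; adjusted p = 0.325 in camera). Of 24 G2/M genes 9 rose (8 adjusted over the list alone) and 4 fell, with CDK1 at 1.93 ± 0.11 and CCNA2 at −0.89 ± 0.06 (adjusted p = 0.469 in camera). The 9 replication-independent histone genes split into 3 up and 3 down (adjusted p = 0.564 in camera), with a median of −0.22, a mean of 0.09 and a test that pointed down. The p53 targets (5 up, 4 down of 14, adjusted p = 0.640 in camera) had a median of 0.12 and a mean of −0.08, and their test also pointed down. The Polycomb list (7 up, 9 down of 21, 7 and 10 adjusted over the list alone, adjusted p = 0.980 in camera) had a median of 0.04, and fry pointed down; CBX2 fell by 1.67 ± 0.08. Markers of other cells were few among tested genes, though not all of them were low. In untreated Karpas-422 CD3G stood at 687 ± 16.3 and DCN at 459 ± 12.1 CPM. CD3D, CD247, CD33, SPI1 and FN1 lay between 3.05 and 67.0 CPM there. The number of tested markers thus says nothing on their levels. Of the B cell identity genes, MS4A1 and CD22 stood at only 6.03 and 6.35 CPM there, before TMM scaling, while POU2F2 stood at 1820 CPM. A gene's CPM in the shallow libraries is therefore not read here as its level of expression. The same limit holds for the members of the lists called in Karpas-422. Of 4 T and NK markers CD3G and CD3D fell and CD247 and TCF7 rose (median 0.50, test down, adjusted p = 0.643 in camera). Of 2 myeloid markers CD33 rose, and of 2 epithelial or fibroblast markers FN1 rose and DCN fell. No globin or mitochondrially encoded gene was tested (0 of each). With library sizes alone the medians of the BCL2 family (0.03), chaperones (0.18) and histone genes (0.19) turned, and with DESeq2's size factors that of the Polycomb list (−0.01).

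The second comparison set the clones labelled BCL11A knockout against the untreated WSU-DLCL2 line. BCL11A RNA stood at 58.8, 69.6 and 51.9 CPM in clones 1 to 3, and at 46.8, 45.7 and 73.5 CPM in untreated replicates 1 to 3. The difference of 0.13 ± 0.21 did not pass the test (adjusted p = 0.915, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), so the RNA level was not lower in the clones. How the gene was disrupted is not given in the sources used here. RNA with a small insertion or deletion can persist, and these counts do not check the labels. The libraries are therefore called the clones labelled BCL11A knockout. No unedited clone is among the samples, so differences that arise from cloning cannot be told apart from loss of BCL11A.

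Against all 3 untreated libraries, MHC class II genes were lower as a list. The list's median was −0.52, and 7 of its 14 genes were called down when adjusted over the list alone (0 over all genes). HLA-DQA1 stood at 64.6, 65.1 and 84.4 CPM in the clones and at 208, 206 and 199 CPM in the untreated libraries, a log2 fold change of −1.52 ± 0.14 (adjusted p = 0.0904, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HLA-DMB, which loads peptide onto class II molecules, had −0.83 ± 0.12, and HLA-DRA −0.73 ± 0.14. In camera the MHC class II list had an adjusted p of 6.82e-11, and 0.0443 with an estimated correlation. No single gene of 16152 was called in edgeR (0), while 1117 had an unadjusted p under 0.05, DESeq2 called 315 and limma-voom 2. The groups did not overlap for 2660 genes (16.5%), where chance gives 10%.

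A further 9 lists were called in this fit with the preset correlation and not with an estimated one. Lower were the NF-kB targets (18 genes, median −0.90, adjusted p = 4.79e-10, and 0.338 with an estimated correlation), of which only CCR7 was called adjusted over the list alone (1). Lower too were ATF4 genes (1.13e-05, and 0.465 with an estimated correlation), cholesterol genes (0.000191, and 0.465), plasma cell genes (0.00684, and 0.488), BCL2 family genes (0.0141, and 0.338), interferon genes (0.0314, and 0.338) and histone acetylation genes (0.0314, and 0.465). Higher were DNA replication genes (median 0.48, adjusted p = 1.51e-06, and 0.523 with an estimated correlation) and G2/M genes (0.0330, and 0.711). Without untreated replicate 3 the DNA replication list had a median of 0.11 and was no longer called (adjusted p = 0.610 in camera), and neither were the plasma cell (0.607), interferon (0.0505) and histone acetylation (0.189) lists.

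Untreated replicate 3 decided these counts. It differed over 2-fold from the mean of replicates 1 and 2 in 2978 of 13033 genes, against 8 genes between replicates 1 and 2. In the planned fit that leaves it out, whose named genes and lists were chosen after the data were seen, 351 of 16607 genes changed (70 up, 281 down), 3150 had an unadjusted p under 0.05, and the groups did not overlap for 6688 genes (40.3%, where chance gives 20% with 3 against 2 libraries). Of the 351 genes, 316 had the same direction with replicate 3 included, and 224 of the 351 had an unadjusted p under 0.05 with it. Any gene not tested with replicate 3 counts as not agreeing. Both fits use the same clones and untreated replicates 1 and 2, so this agreement is no independent support for the calls.

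In that fit the calcium/calmodulin-dependent kinase gene CAMK4 was at 0.194 ± 0.0101 CPM in the clones (n = 3) and at 14.5 ± 0.455 CPM in untreated replicates 1 and 2 (n = 2), a log2 fold change of −6.21 ± 0.18. The death receptor gene FAS fell from 19.2 ± 1.10 to 1.91 ± 0.738 CPM, and CD80, a costimulatory ligand of T cells, from 11.1 ± 0.634 to 0.840 ± 0.332 CPM. GCA (−4.72 ± 0.66), NIBAN1 (−3.62 ± 0.35) and the focal adhesion gene ZYX (−3.25 ± 0.19) fell as well. Higher were AK5 (2.80 ± 0.32), FNDC1 (2.73 ± 0.42), LGALS9 (2.42 ± 0.28) and the Hedgehog pathway factor GLI3 (1.97 ± 0.15). IRF4, a transcription factor of activated B cells, fell by 3.41 ± 0.42 (adjusted p = 0.0201, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the kinase gene SYK of B cell receptor signalling rose by 0.70 ± 0.06. Replicate 3 lay with the clones for several of these genes: FAS stood at 0.973 CPM in it, against 18.5 and 20.1 CPM in replicates 1 and 2.

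Of 19 NF-kB targets, 11 fell in this fit, 0 rose and 8 were not called, and 15 fell adjusted over the list alone. BCL2A1, an anti-apoptotic target, fell by 2.62 ± 0.17, LTA by 1.32 ± 0.07 and BIRC3 by 1.56 ± 0.11 on the log2 scale. The list's median was −1.29, with an adjusted p of 4.31e-44 in camera and 0.0125 with an estimated correlation. The untreated library left out lay with the clones here: 15 of 17 NF-kB targets were lower in it than in replicates 1 and 2 (median −1.16). Of 14 MHC class II genes 6 fell (12 adjusted over the list alone), with HLA-DQA1 at −1.53 ± 0.13, HLA-DMB at −0.75 ± 0.07 and HLA-DPB1 at −0.72 ± 0.07 (adjusted p = 1.49e-14 in camera, and 0.165 with an estimated correlation). For HLA-DPB1 untreated replicate 3 lay with the clones, at 85.2 CPM against 145 and 146.5 CPM in replicates 1 and 2; over the list its median difference was −0.10. Of 20 ATF4 genes 3 fell (16 adjusted over the list alone), with PSAT1 at −0.85 ± 0.09, MTHFD2 at −0.65 ± 0.07 and ASNS at −0.66 ± 0.10 (adjusted p = 3.92e-16, and 0.165 with an estimated correlation). Of these, 18 of 20 were lower in untreated replicate 3 as well (median −0.99). The G2/M genes, higher with replicate 3, were lower without it (adjusted p = 0.000312, and 0.328 with an estimated correlation). Other calls with the preset correlation alone were the BCL2 family (2 of 16 down, adjusted p = 0.00213), MYC targets (higher, 0.00284), cholesterol genes (0.0311), germinal centre genes (0.0450) and T and NK markers (0.0450). The last 3 were lower, and the adjusted p of these 5 lists with an estimated correlation lay between 0.211 and 0.711. MYC itself (0.11 ± 0.12), BCL2 (−0.49 ± 0.22), BCL6 (−0.29 ± 0.12), EZH2 (−0.09 ± 0.06), EP300 (−0.03 ± 0.06) and CREBBP (0.25 ± 0.09) did not pass the test. BCL11A was at 0.37 ± 0.12 (adjusted p = 0.177, same test).

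**Figure D3:**
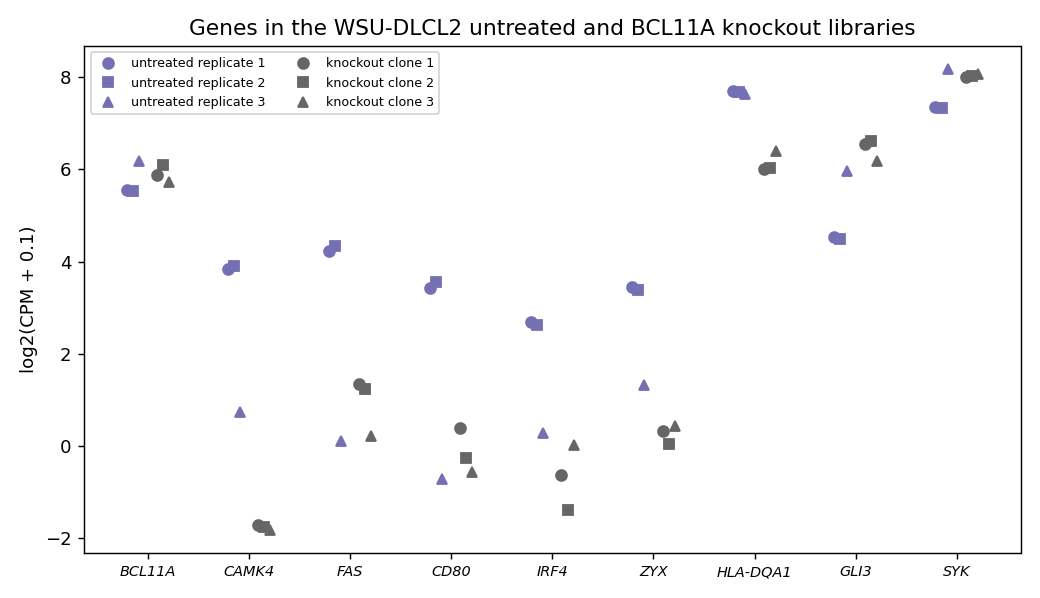
Log2 of CPM plus 0.1 for 9 genes in the 6 deep libraries of WSU-DLCL2. Each point is a library, by group; BCL11A overlaps between the clones and the untreated libraries, HLA-DQA1 lies between 64.6 and 84.4 CPM in the clones and between 199 and 208 CPM in the untreated libraries, and FAS is at 0.973 CPM in untreated replicate 3.

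The third comparison put A-485 against untreated cells in WSU-DLCL2, across the 2 kinds of library. Genes of the pseudoautosomal region, which lies on both sex chromosomes, had the largest rises. P2RY8 was at least 24646-fold higher with A-485, SLC25A6 at least 22349-fold, DHRSX at least 1179-fold, PPP2R3B at least 678-fold and PLCXD1 at least 331-fold (floor of 3 counts over the group). Those genes had 0 counts in all 6 deep libraries, whether untreated or clones, and P2RY8 stood at 1008 CPM, before TMM scaling, in untreated Karpas-422. Each shallow library, untreated Karpas-422 included, held at least 1962 counts of P2RY8 and 3328 of SLC25A6. These differences thus followed the kind of library also where no A-485 was given. CD99 had 1 count over the untreated libraries and a ratio of 4442 (95% counting interval 795 to 175639). The genes with the largest falls were at 0 in all libraries with A-485. SBNO1 was at least 1493-fold lower, NLRP11 683-fold, WDR5 565-fold, MYADML2 439-fold, TGIF2 355-fold and RBMXL1 292-fold. Of these, SBNO1, NLRP11, WDR5, MYADML2 and RBMXL1 were at 0 in all Karpas-422 libraries too, while SBNO1 stood at 250.1 ± 15.8 CPM in the clones.

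The genes fixed beforehand gave values of the same confounded kind. MYC stood at 1.60 ± 0.715 CPM with A-485 and at 308 ± 51.7 CPM without, beside 5.49 CPM, before TMM scaling, in the untreated Karpas-422 libraries, which are shallow like the former. BCL6 fell by 5.33 ± 0.22 and EZH2 by 1.92 ± 0.36, while IRF4 rose by 3.63 ± 0.60, EP300 by 2.54 ± 0.16 and BCL2 by 0.58 ± 0.12. BCL11A differed by 0.16 ± 0.18 (adjusted p = 0.445, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and CREBBP by 0.32 ± 0.23 (adjusted p = 0.237, same test). Without untreated replicate 3 both were called up, BCL11A at 0.39 ± 0.09 (adjusted p = 0.000252, same test) and CREBBP at 0.67 ± 0.09 (adjusted p = 1.33e-08, same test). Cholesterol biosynthesis was the list called: 18 of 22 genes fell and 2 rose, also adjusted over the list alone, with FDFT1 at −4.71 ± 0.14, INSIG1 at −6.31 ± 0.20 and HMGCS1 at −6.08 ± 0.21. Its adjusted p in camera was 0.0255, and 0.970 with an estimated correlation. Before TMM scaling FDFT1, INSIG1 and HMGCS1 stood at 26.9, 2.83 and 6.93 CPM with A-485. They stood at 19.0, 1.99 and 7.27 CPM in untreated Karpas-422, which is shallow too, and at 660, 214 and 378 CPM in the clones. The falls of these 3 genes thus followed the kind of library also without A-485, and the call is not a response to A-485 alone. Of 16 interferon genes 6 rose and 6 fell (median 0.18, mean −0.34), with CMPK2 at −4.08 ± 0.31, and the list was not called (adjusted p = 0.846).

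In all, 12121 of 14632 genes were called (5105 up, 7016 down), and the groups did not overlap for 12577 genes (86.0%, with 10% by chance). Without untreated replicate 3, 12704 of 13638 genes were called (5506 up, 7198 down), and the G2/M list was called beside cholesterol (both adjusted p = 0.0261 in camera, and 0.938 with an estimated correlation). Library sizes alone moved the median of all genes by −0.16, and DESeq2's size factors by 0.22. The fold change fell with the number of annotated transcripts, from a median of 1.11 for genes with 1 transcript to −2.25 for those with over 20 (Spearman's rho −0.317 over 14218 genes). The same rho was −0.0755 over 15704 genes in the knockout comparison.

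**Figure D4:**
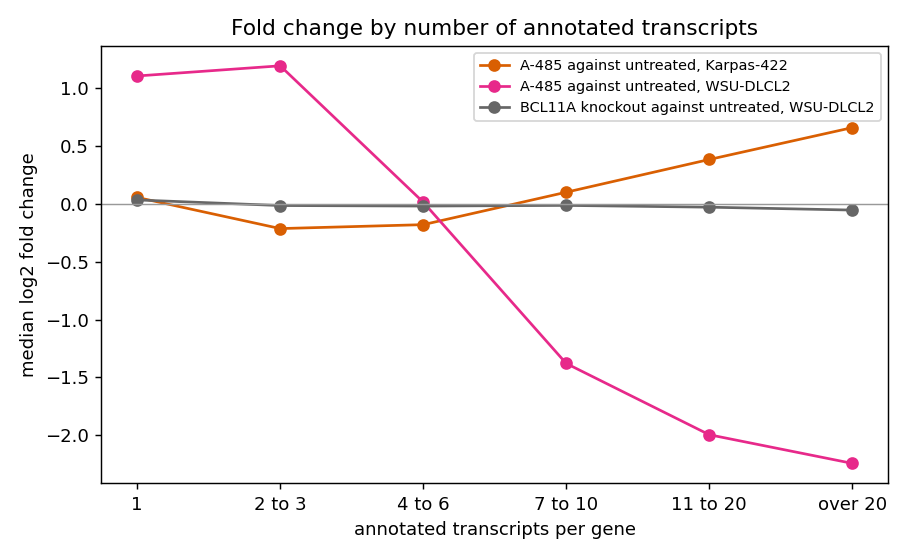
Median log2 fold change of genes grouped by the number of annotated transcripts, for A-485 in Karpas-422, A-485 in WSU-DLCL2 and the clones labelled BCL11A knockout. In WSU-DLCL2 with A-485, compared across the 2 kinds of library, the medians run from 1.11 for genes with 1 transcript to −2.25 for genes with over 20.

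Whether the response to A-485 differed between the lines was tested as an interaction, which carries the same confounding. BCL11A differed by 1.49 ± 0.19 (WSU-DLCL2 minus Karpas-422), EP300 by 2.44 ± 0.20, BCL2 by 0.96 ± 0.15, EZH2 by −4.33 ± 0.43, MYC by −3.67 ± 0.52 and BCL6 by −4.64 ± 0.22. CREBBP (−0.08 ± 0.25, adjusted p = 0.828, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and IRF4 (4.13 ± 2.32, adjusted p = 0.130, same test) did not pass. In total 10521 of 14680 genes differed (4385 higher and 6136 lower in WSU-DLCL2). With library sizes alone the median moved by −0.56, and with DESeq2's size factors by 0.35.

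Both lines shared some calls, but those of WSU-DLCL2 were made across the 2 kinds of library, so they are not shared responses to A-485 alone. IFIT2 rose by 2.64 ± 0.08 in Karpas-422 and by 2.77 ± 0.53 in WSU-DLCL2, and the interferon gene IFI27 by 2.70 ± 0.39 and 2.38 ± 0.41. In WSU-DLCL2 these 2 genes were low, at 0.435 and 0.576 CPM untreated and at 2.92 and 2.97 CPM with A-485. CDKN2B, a cyclin-dependent kinase inhibitor gene, rose by 3.18 ± 0.17 and 2.77 ± 0.39, and RGS17, TPH1 and LHX4 rose in both as well. MYC (−3.89 ± 0.29 and −7.58 ± 0.31), NLRP4, LRIG1, SERPINA9, AHNAK2 and MGLL fell in both. Among 11055 genes tested in both lines, 1470 rose in both and 1215 fell in both, fewer than the 1673 and 1606 of independent lists (Fisher's exact test, two-sided, p = 3.48e-16 and 1.76e-57), and 3836 went opposite ways. The fold changes correlated across genes at r = −0.0326. With library sizes alone the shared calls split into 2225 up and 695 down.

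A-485 and the knockout label in WSU-DLCL2 shared 0 calls among 14251 genes with all untreated libraries, since edgeR called 0 genes for the clones. Without untreated replicate 3, 26 genes rose and 142 fell in both, beside 24.6 and 122 for independent lists (Fisher's exact test, two-sided, p = 0.699 and 0.00732), and 96 went opposite ways. The covariance of the fold changes was 0.195, beside 0.00641 in 50 simulations of unchanged groups, and r was 0.126 beside 0.425. With replicate 3 the covariance was 0.0884 beside 0.106 simulated, and r 0.0575 beside 0.475. In each simulation all libraries were drawn anew, and both comparisons shared the simulated untreated ones. Every group took its means and spread from the untreated libraries. The difference in kind of library and the clones' own spread were thus left out, so the simulated values cannot decide whether the observed covariance is in excess. The untreated libraries are too few to be split, so part of any excess may come from sharing them, and the difference in kind of library enters the A-485 side alone.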

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

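The tests on the genes at least 32-fold lower in WSU-DLCL2 with A-485, and the one on genes with 1 annotated transcript in Karpas-422, were chosen only after the results were seen, as were the comparison of replicate 3's r with that of the libraries labelled A-485 and the sorting of the interaction's splits; the other tests of this part were written down before. The response to A-485 differed between the lines in 10521 genes by the interaction test. Among the fixed genes, the log2 difference (WSU-DLCL2 minus Karpas-422) was 1.49 for BCL11A, 2.44 for EP300, −4.33 for EZH2, −3.67 for MYC, 0.96 for BCL2 and −4.64 for BCL6. In data outside the tests, reads outside genes made up 17.9% in Karpas-422 with A-485 and 9.28% in its untreated libraries, and reads without a unique alignment 50.8% in WSU-DLCL2 with A-485 and 8.61% in its untreated libraries.

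In WSU-DLCL2, 1520 genes were at least 32-fold lower with A-485. A response to A-485 with no effect of the kind of library is argued against: over these genes the median log2 ratio of WSU-DLCL2 with A-485 to untreated Karpas-422, which is of the same kind of library, was 0 (quartiles −0.51 and 0.56), though the lines differ. The 2 kinds of library differed also where no A-485 was given. All deep libraries had 0 unaligned reads and 0 counts of P2RY8. Each shallow one, untreated Karpas-422 included, had at least 2.51% unaligned and 1962 counts of it. Libraries made or counted in different ways thus remain a candidate explanation for all or part of the fall. Untreated Karpas-422 was also far below the clones over these genes, with no A-485 on either side. The median log2 ratio was −5.76, against −1.57 over all genes tested. Loss of reads shared by several transcripts of a gene may account for the protein-coding part, where 1.68% of 1074 genes had 1 annotated transcript against 5.04% of all tested, but not for the 432 genes of other types, where 90.5% had 1 against 69.8% (genes without a transcript number left out). Of the 1520 genes, 356 were processed pseudogenes, which resemble other genes. Loss of reads without a unique alignment was not tested for them. A part of the fall due to A-485 stays open, because treatment and kind of library are confounded in this line.

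In Karpas-422 the share of reads outside genes was higher with A-485 while 71.4% of genes were called. Genomic DNA in the A-485 libraries stays open. Summed over 350 olfactory receptor genes, which are seldom transcribed, counts rose from 1.72 ± 0.392 to 4.69 ± 0.567 CPM. That was 0.115 (SE 0.0154) of the rise computed for genomic DNA. The computed rise takes every read of these genes as counted. They have many paralogs and may lose reads without a unique alignment, so the test cannot decide. A count restricted to reads that tell transcripts apart is argued against as the whole cause, as 75.8% of 484 genes with 1 annotated transcript were called. A response to A-485, including more unspliced or intergenic RNA, stays open and was not tested.

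Untreated WSU-DLCL2 replicate 3 stood apart from replicates 1 and 2, with an SD of the log2 difference of 0.941 over 13033 genes, against 0.163 between those 2 replicates. Treatment with A-485, as its treatment entry says, stays open: r between its difference and the A-485 fold change in Karpas-422 was −0.00788 (10062 genes; −0.146 over 391 genes with 1 annotated transcript), but it was −0.0326 for the WSU-DLCL2 libraries labelled A-485 throughout, so the test cannot decide. DNA replication and ATF4 genes were lower in this library (medians −2.07 and −0.99), as with A-485 in Karpas-422. The other lists called there moved less or the other way. MYC targets (0.59), B cell identity (0.59) and plasma cell genes (0.54) were higher, against medians of −1.76, −0.53 and −0.58 in Karpas-422. Interferon (0.05), germinal centre (0.14) and MHC class II genes (−0.10) lay near 0, against 1.79, −0.81 and −0.81 there. A transcript length bias cannot be told apart from other causes, since Spearman's rho with exonic length was 0.138 over 12775 genes and a single library does not separate length from a real change. Another culture state or another label error stay open and were not tested.

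The 6 libraries of each comparison of groups form 10 splits, too few for a share under 0.05. The real split gave 8457 genes in Karpas-422 and 12121 for A-485 in WSU-DLCL2, each 1 of 10 splits with as many, with 0 as the highest of the others; the knockout gave 0 in 10 of 10. For the interaction, 1 of 100 splits drawn gave as many genes, the real one with 10521, and the highest other gave 8951. The 93 splits that mixed the WSU-DLCL2 groups, and with them the kinds of library, gave 0 to 130 genes. Mixing puts the difference between the kinds into the spread within groups, so few calls were bound to result and decide nothing. The same holds for the other splits of A-485 in WSU-DLCL2. The 6 drawn splits of the interaction that kept the WSU-DLCL2 groups whole gave 8682 to 8951, and are too few for a share under 0.05.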

How the results depend on the processing

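The fits on genes with 1 annotated transcript were chosen after the data were seen; all other alternatives were planned. Counts moved by over 1.5 times as follows, and except where fewer genes, fewer samples or a stricter threshold explain it, the cause was not tested. On genes with 1 annotated transcript, where fewer are tested, the counts were 367 (Karpas-422), 256 (A-485 in WSU-DLCL2), 2 (knockout), 296 (interaction), 82 (both lines) and 2 (A-485 and knockout). A log2 fold change of at least 1 left 4090 genes in Karpas-422 and 1142 shared by both lines. For the knockout (0 by edgeR, 1117 unadjusted), no filter gave 20, DESeq2 315, limma-voom 2 and all 15 libraries in 1 fit 306; the genes shared with A-485 were then 14 without a filter, 157 by DESeq2 and 155 with all 15 libraries. Lists called in Karpas-422 (8) were 3 with an estimated correlation and 19 by fry; in WSU-DLCL2 with A-485 (1) 0, 14, and 6 without a filter; for the knockout (10) 1 and 2.

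Leaving out each library gave 7907 to 8840 genes in Karpas-422, 10959 to 12704 for A-485 in WSU-DLCL2, 0 to 351 for the knockout, 10193 to 11547 for the interaction, 2427 to 2956 for both lines and 0 to 168 for A-485 and knockout. Lists called ranged from 8 to 9, 1 to 2 and 8 to 12. The highest counts of genes outside Karpas-422 alone came without untreated WSU-DLCL2 replicate 3.

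Deviations of libraries with the same replicate number correlated at 0.0152, 0.0638 and −0.0430 in Karpas-422, −0.00627, 0.0129 and −0.00380 for A-485 in WSU-DLCL2 and 0.103, 0.0310 and 0.226 for the knockout, and not every library correlated best with its own number, so no pairing was used. With the replicate number as a block the counts were 8250, 12051, 0, 10380 (interaction), 2572 (both lines) and 0 (A-485 and knockout), and the lists 9, 1 and 9.

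For named genes, BCL2 in Karpas-422 turned to 0.0303 with library sizes alone, and HLA-DRB1 (−1.01) and H1-2 (−0.28) turned in the interaction on genes with 1 annotated transcript; the cause was not tested. Of the fits of single named genes, 1103 of 1112 kept their side of the threshold in Karpas-422, 1132 of 1136 for A-485 in WSU-DLCL2, 917 of 958 for the knockout (41 became called) and 1631 of 1644 for the interaction.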

Other observations

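The overlap of A-485 in Karpas-422 with the knockout was chosen after the data were seen, as were the lists of untreated WSU-DLCL2 replicate 3. These 2 comparisons share neither libraries nor kind of library. Without untreated WSU-DLCL2 replicate 3, 58 genes fell in both, beside 46.9 for independent lists (Fisher's exact test, two-sided, p = 0.0466), and 10 rose in both, beside 16.0 (p = 0.0592); with 2 tests neither p is small after adjustment, and 56 genes went opposite ways. Among those that fell were the phosphatase genes DUSP2 (−4.37 ± 0.20 in Karpas-422 and −1.39 ± 0.10 in the clones) and DUSP5 (−1.44 ± 0.11 and −2.09 ± 0.15), the kinase gene SRC (−1.59 ± 0.31 and −2.90 ± 0.25), TSC22D3 (−2.35 ± 0.34 and −1.49 ± 0.24) and HLA-DQA2 (−1.40 ± 0.07 and −1.67 ± 0.13), a class II gene with close paralogs. SESN3 (0.57 ± 0.06 and 1.57 ± 0.14) and AACS (1.78 ± 0.17 and 0.65 ± 0.08) rose in both. Across 11131 genes the fold changes correlated at r = −0.0573.

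Untreated WSU-DLCL2 replicate 3, compared with the mean of replicates 1 and 2, differed by gene group. This describes these libraries and has no replicate. All 24 DNA replication genes were lower in it, with a median log2 difference of −2.07: CDC45 stood at 4.23 CPM in replicate 3 and at 87.2 and 86.3 CPM in replicates 1 and 2, and MCM2 at 52.2 against 349 and 368 CPM. All 24 G2/M genes were lower as well (median −1.13), as were 18 of 20 ATF4 genes (−0.99) and 15 of 17 NF-kB targets (−1.16); each median lay at percentile 0 of 10000 random lists matched on expression. Higher were 15 of 17 endoplasmic reticulum chaperones (median 1.16), with HSPA5 at 1104 against 215 and 230.2 CPM, 18 of 22 MYC targets and ribosome biogenesis genes (0.59) and 19 of 22 B cell identity genes (0.59), each at percentile 100. The random lists drew each gene separately and kept no correlation between the members of a list. With 1 library, the percentiles therefore do not measure how unusual these shifts are.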
